A study of Mus musculus with 4 samples.

How the data were processed

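Single-nucleus chromatin accessibility was measured with the 10x Chromium Single Cell ATAC v2 kit in frozen hippocampus of female C57BL/6J mice, in 4 libraries, 1 per combination of genotype (wild type or APP NL-G-F) and exercise (rest or running wheel). The sample titles name RNA sequencing, whereas the molecule (genomic DNA), the kit and the peak coordinates are those of chromatin accessibility, and the series describes both kinds of data. RNA data were not analysed here. Per the labels, reads were processed with Cell Ranger 3.1.0 on mm10, with no role or order given. How peaks were called, how nuclei were chosen and how the values were made binary was not given in the sources used here. The deposited values are binary calls, 1 where a peak was open in a nucleus and 0 otherwise, for 328455 peaks in 31793 nuclei. Stored zeros made up 0.0894% of the 212165682 stored entries, and the values held no read or fragment counts. The analysis had been planned for counts, so calls were summed over nuclei in their place and no count model was fitted. Nuclei were assigned to libraries by the prefix of their barcode names, which was WTRT, WTEX, ADRT or ADEX. The series text abbreviates the conditions as WT_RT, WT_EX, APP_RT and APP_EX. AD was read as the knock-in because it is the only genotype other than WT, and RT as rest because EX is exercise. This reading rests on the names alone. The number of measured columns not used was 0.

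Every nucleus passed the planned minimum of 1000 open peaks. The 50000 most often open peaks were weighted by term frequency and inverse document frequency and reduced to 30 components by singular value decomposition. The component that followed depth most (r = 0.934 with log10 depth), which was the first, was left out. Doublets were scored from simulated pairs of nuclei, and 0.8% per 1000 nuclei of each library were removed, which was 593, 454, 650 and 353 nuclei in the order wild type at rest, wild type with exercise, knock-in at rest and knock-in with exercise. Nuclei were joined by 15 nearest neighbours and clustered with the Leiden method at resolution 1. A cluster was named when it had at least 100 nuclei, a median doublet score of at most 0.5 and a median log2 enrichment of at least 0.4 over at least 3 markers of a list. Of 43 clusters, 12 were named, 7 with at least 20 nuclei were not, and 24 had fewer than 20 nuclei. The unnamed nuclei were counted in the library totals behind the shares. Leading genes of the granule-like clusters included Dsp (cluster 1) and Prom2 (cluster 2), of the oligodendrocyte-like clusters Mag and Opalin (cluster 3) and Cldn11 (cluster 5), and of the pyramidal-like clusters Htr1b (cluster 6), Tshz2 (cluster 8), Plcxd3 (cluster 11) and Cpne7 (cluster 12). Tyrobp and Hhex led the microglia-like, Slc7a10 the astrocyte-like, Kcnmb2 the inhibitory-like and Pdgfra the precursor-like cluster.

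The accessibility of a gene was the sum of open calls over the peaks in its body and 2 kb on both sides, because the gene table gave no strand to place an upstream side. Of all peaks, 59.3% fell in a gene window and 2.37% in more than 1. Sums were expressed per 1000000 open calls of the class and library (CPM), and log2 ratios used a pseudocount of 0.5. The 4 comparisons were genotype at rest, exercise in wild type, exercise in the knock-in and genotype with exercise. Comparisons that share a library are not independent, such as genotype at rest and exercise in wild type, which share wild type at rest. Intervals for levels, shares and ratios of summed calls were exact Poisson and binomial intervals. Those for ratios of shares used a normal approximation on the log scale, and those for list medians came from 2000 draws of Poisson counts. Because each group had 1 library, no p-value was computed from nuclei. Each list was placed among 10000 random lists matched in 20 bins of accessibility.

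The 21 gene lists, fixed before the data were examined, were immediate early, late activity-regulated, exercise and growth factors, neurogenesis, oxidative phosphorylation, glutamate synapse, GABA synapse, heat shock, Alzheimer risk homologues, circadian, glucocorticoid-responsive, disease-associated microglia, homeostatic microglia, interferon response, plaque-induced, reactive astrocyte, homeostatic astrocyte, disease-associated oligodendrocyte, myelin, cholesterol synthesis and vascular genes. The vascular list was not compared because no cluster met the rule for a vascular class. The design, the marker lists, the other settings to be tried and the rule for naming genes were also fixed then. That rule named, in each class and comparison, the 2 highest and 2 lowest genes among those with at least 200 summed calls per library on average and an interval that excluded no difference, and the highest and lowest member of each list. Other list members in the text, such as Igf1, P2ry12 and Bdnf, were chosen as examples after their values were seen, as was App in astrocyte-like nuclei.

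Depth limited what small classes could show. Granule-like sums held 19042960 and 15757083 calls in the wild-type libraries, whereas astrocyte-like classes of the knock-in held 277 and 229 nuclei. Median open peaks also differed between groups within a class, for example 3863, 3101, 3234 and 2733 in oligodendrocyte-like nuclei and 7360, 6812, 5758 and 5847 in microglia-like nuclei. The other settings tried were a minimum of 3000 open peaks, no removal of doublets, resolutions of 0.5 and 2, 20 and 50 components, peaks within 2 kb of either gene end alone, median-of-ratios size factors, thinning to 2000 open peaks, a minimum of 200 calls for list members and a minimum of 500 in place of 100 calls per peak. Matching of nuclei in depth, shares among glial classes alone and outside the microglia-like class, single granule clusters and removal of genes in divergent segments were added after seeing the data. Motifs were not analysed here because no genome sequence was used.

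The intervals, lists and correlations were run on simulated data made from the granule-like and microglia-like sums. In each class 200 genes were changed by 1.5-fold or 2-fold. Intervals excluded no difference for 100% and 98.7% of those changed 1.5-fold and for 4.74% and 4.43% of unchanged genes. A list of 20 changed genes lay at percentile 100 in both classes, and a list of 20 unchanged genes at 16.4 (granule-like) and 94.2 (microglia-like). Correlations between pairs of ratios with no simulated effect were between -0.002 and 0.011. The simulated counts were Poisson draws around the pooled rate of each gene, with no added variation between nuclei or libraries. The share for unchanged genes and these correlations therefore followed from that setting. They do not show how intervals or correlations behave where libraries differ for other reasons. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.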

Results

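Open chromatin was measured in single nuclei from the frozen hippocampus of female C57BL/6J mice. The mice were either wild type or carriers of APP NL-G-F, a knock-in of familial Alzheimer's disease mutations into the mouse amyloid precursor gene App. Mice of each genotype were kept without exercise, called rest here, or with a running wheel for 10 weeks from 8 weeks of age. Each of the 4 groups had 1 library, so there were no replicates and no test between groups was made. The number of mice behind each library was not given in the sources used here. The libraries held 8607 nuclei (wild type at rest), 7530 (wild type with exercise), 9013 (knock-in at rest) and 6643 (knock-in with exercise). Their total numbers of open calls, a call being 1 peak open in 1 nucleus, were 59900379, 52215984, 55916365 and 43943282. The median number of open peaks per nucleus was 6184, 6375, 5436 and 6025 in the same order. Intervals in parentheses are 95% intervals for counting error only and do not cover differences between mice.

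The nuclei fell into 7 classes with the marker genes of dentate granule neurons, pyramidal neurons, inhibitory neurons, oligodendrocytes, oligodendrocyte precursors, astrocytes and microglia. These classes held 28597 of the 29743 nuclei kept after removal of doublets, and all of them are named here as resembling a cell type ("granule-like"). Of the 4 pyramidal-like clusters, numbers 6, 8 and 12 (1948, 1476 and 618 nuclei) were named by markers of subicular or cortical excitatory neurons and number 11 (1007 nuclei) by markers of CA3 pyramidal neurons. Nuclei outside the classes, mostly in clusters with high doublet scores, made up 4.60%, 4.08%, 3.67% and 2.88% of the libraries in the order above. Granule-like nuclei were the largest class, with 36.6%, 30.7%, 33.3% and 33.2% of nuclei.

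App itself, on chromosome 16 from 84952666 to 85175255 (mm10 coordinates), had 78 peaks. In granule-like nuclei its accessibility was 227 CPM (open calls per 1000000 calls of the class and library), with an interval of 220 to 234, in wild type at rest, 222 (215–230) in wild type with exercise, 228 (221–235) in the knock-in at rest and 225 (218–233) in the knock-in with exercise. Oligodendrocyte-like nuclei had the highest level of App of the 7 classes, with 529, 530, 531 and 552 CPM in that order. In microglia-like nuclei the levels were 284, 282, 261 and 280. Pyramidal-like nuclei had 268, 282, 261 and 265, inhibitory-like nuclei 334, 354, 305 and 346, and precursor-like nuclei 220, 204, 225 and 248. Astrocyte-like nuclei had 91.8, 94.7, 89.0 and 134, the last of these with an interval of 117 to 154. Accessibility of App does not show whether the coding mutations of the knock-in were present.

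**Figure D1:**
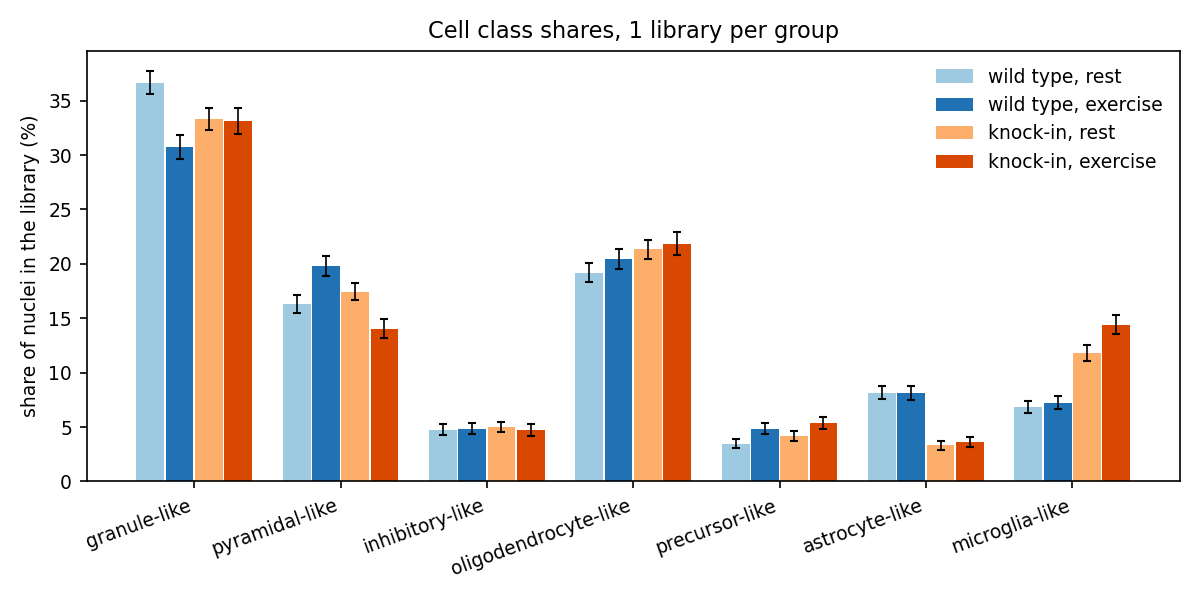
Share of nuclei per class (vertical axis, percent of the nuclei kept in each library) for the 4 groups, 1 library each; bars start at 0 and error bars are exact 95% binomial intervals. Microglia-like nuclei made up 6.83% and 7.22% of the wild-type libraries and 11.8% and 14.4% of the knock-in libraries, while astrocyte-like nuclei made up 8.17% and 8.11% against 3.31% and 3.64%.

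The first comparison asked how the knock-in hippocampus differed from wild type without exercise. Microglia-like nuclei, the brain's resident immune cells, made up 11.8% (11.1–12.5) of the knock-in library and 6.83% (6.28–7.40) of the wild-type library, a ratio of 1.73 (1.56–1.91). Astrocyte-like nuclei made up 3.31% (2.94–3.72) against 8.17% (7.58–8.80), a ratio of 0.405 (0.353–0.465). In microglia-like nuclei, 17 of the 20 genes of the disease-associated microglia list, a state described around amyloid plaques, were more accessible in the knock-in. Spp1, which encodes the secreted protein osteopontin, was at 19.8 CPM (16.4–23.8) against 4.00 (2.29–6.50), and Igf1, an insulin-like growth factor, at 20.9 against 5.26. Lpl, a lipoprotein lipase, was at 31.2 against 10.8, and the cystatin gene Cst7 at 21.6 against 8.51. The median log2 ratio of the list was 0.30 (0.20–0.41), at percentile 100 of 10000 random gene lists of like accessibility, a description of these libraries and not a test. With members under 200 calls left out the median was 0.19. Summed markers of oligodendrocyte precursors were also higher in microglia-like nuclei of the knock-in, with a log2 ratio of 0.31 (0.16–0.47), while those of oligodendrocytes had 0.11 (0.04–0.19) in the sum and a median of -0.32 over 11 markers. The sums of microglial (-0.10, -0.14 to -0.06), endothelial (-0.15, -0.24 to -0.06) and dentate granule markers (-0.12, -0.20 to -0.03) were lower there and that of astrocyte markers (0.12, 0.03–0.21) higher, with medians over the endothelial and astrocyte markers of 0.25 and -0.04.

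Homeostatic microglia genes were lower in the knock-in at rest in 12 of 15 members, with a median log2 ratio of -0.11 (-0.17 to -0.05). Tmem119, a microglial surface protein, was at 62.5 CPM (56.2–69.3) against 83.3 (74.6–92.8), and P2ry12, the purinergic receptor of surveying microglia, at 291 (277–305) against 329 (312–348). The fractalkine receptor Cx3cr1 was at 208 in both libraries, and the transcription factor Mef2c was higher, at 460 against 430. The interferon response list was higher in 11 of 15 members, with a median log2 ratio of 0.25 (0.11–0.37). Ifi44, an interferon-induced gene, had 28 calls in the knock-in and 1 in wild type, a log2 ratio of 3.72 (1.69–9.64). With each nucleus thinned to 2000 open peaks the interferon median was 0.05. Plaque-induced genes were lower in 9 of 14 members, with a median of -0.04 (-0.10 to 0.06). In other members of the disease-associated list, Csf1, a growth factor for microglia, had a log2 ratio of 0.71 and Clec7a, a pattern recognition receptor, of 0.94. Ctsd, a lysosomal protease, was lower, with a log2 ratio of -0.25 (-0.41 to -0.09).

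Among all microglial genes with an average of at least 200 calls per library, Ccdc85a (log2 ratio 2.15, 1.69–2.67) and Dpys, a pyrimidine-degrading enzyme (1.83, 1.48–2.21), had the highest ratios at rest. Rbpms, an RNA-binding protein (-0.95, -1.21 to -0.71), and Tmem204 (-0.72, -0.91 to -0.53) had the lowest. Ccdc85a and Tmem204 lie in divergent segments, which are 27 windows of 10 Mb where 4 or more peaks, summed over the 7 classes, differed from the wild-type libraries by more than 1.5 on the log2 scale in a knock-in library. A window could qualify through either knock-in library, and that of Ccdc85a held 0 such peaks at rest and 27 with exercise. Without the genes of all divergent segments the disease-associated microglia median was 0.37 in place of 0.30. Microglial marker genes as a group were slightly lower in this class in the knock-in, with summed levels of 2086 against 2236 CPM.

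In granule-like nuclei the differences at rest were small for every gene list. Late activity-regulated genes, induced hours after neuronal firing, had a median log2 ratio of 0.06 (-0.00 to 0.11) and were higher in 8 of 11 members, Scg2 with 0.29 (0.08–0.50). With nuclei thinned to 2000 open peaks that median was -0.02. Immediate early genes had a median of -0.03, and 10 of 17 were lower, Ier2 with -0.28. The largest ratios belonged to Gm52481 (2.68, 2.42–2.95), a predicted gene annotated on chromosome Y in libraries of female mice, and Gm40369 (1.37), in a divergent segment of chromosome 6. Qpct, a glutaminyl cyclase (-0.82), and Tbl3 (-0.80), both in divergent segments of chromosome 17, had the lowest. The window of Gm40369 held 0 peaks past the limit for these segments in the knock-in at rest and 10 in the knock-in with exercise. With peaks near gene ends alone the ratio of Qpct was 0.25, so its sign rests on the gene body. Cluster 1 held 64.8% of granule-like nuclei in wild type at rest and 62.3% in the knock-in at rest. In pyramidal-like nuclei Gm52481 (2.91) and Gm40369 (1.36) were again highest, and Ren1, which encodes renin (-0.63), and Disp1 (-0.59) were lowest. Of these, Gm40369 and Ren1 lie in divergent segments of chromosomes 6 and 1. In the genotype comparison with exercise Disp1 had -0.145 (-0.3 to 0.007), whereas Gm52481 had 1.16, Gm40369 1.64 and Ren1 -0.48. Late activity-regulated genes were higher in 9 of 11 members in pyramidal-like nuclei, with a median of 0.08 (0.02–0.15). Of these nuclei, cluster 8 held 33.5% in the knock-in and 23.5% in wild type, and cluster 6 held 35.6% and 42.3%.

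Oligodendrocyte-like nuclei at rest had higher accessibility in the knock-in at Col4a1, a basement membrane collagen (log2 ratio 1.09, 0.83–1.37), and Alk, a receptor tyrosine kinase (1.07, 0.86–1.29). Pkmyt1 (-1.21) and 1520401A03Rik (-1.17) were lower, and all 4 genes lie in divergent segments of chromosomes 8 and 17. The disease-associated oligodendrocyte list was split, with 5 of 10 members higher and a median of 0.01 (-0.06 to 0.23). Its antigen presentation genes H2-K1 (25.4 against 11.5 CPM) and H2-D1 (33.3 against 18.4) lie on chromosome 17 in divergent segments, and the protease inhibitor gene Serpina3n was at 29.7 (25.6–34.2) against 22.4 (18.9–26.4). Homologues of Alzheimer risk genes were higher in 16 of 21 members in this class (median 0.14, 0.02–0.20), and among those with at least 200 calls per library on average Cd2ap, in a divergent segment of chromosome 17, was highest (0.60, 0.40–0.80). Myelin genes had a median of 0.00 (-0.06 to 0.03), with 9 of 16 higher, and cholesterol synthesis genes of -0.01, with 6 of 16 higher. The oligodendrocyte-like share was 21.3% against 19.2%, a ratio of 1.11 (1.05–1.18) that was 0.955 among nuclei with at least 3000 open peaks. Cluster 5, a shallow part of this class with a median of 1824 open peaks, held 31% of it in wild type and 37.6% in the knock-in.

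Astrocyte-like nuclei at rest had a reactive astrocyte median of 0.08 (-0.07 to 0.20), with 9 of 14 members higher. Gfap, the glial filament protein of reactive astrocytes, was at 98.4 CPM (83.2–116) against 83.9 (75.2–93.3), which was not a detectable difference at this depth. Homeostatic astrocyte genes had a median of 0.01 (-0.09 to 0.06), although Slc1a2, the main glutamate transporter, was at 379 against 434. Spats2l (0.49) and Kazn (0.49) were highest, and Vit, an extracellular matrix protein (-1.05), and Kbtbd11 (-0.58) were lowest. Both of the latter lie in divergent segments, and Vit had a ratio of 2.17 from peaks near its gene ends alone. In the genotype comparison with exercise Spats2l had 0.14, Kazn 0.23 and Kbtbd11 -0.16, with intervals that included 0, while Vit had -0.74. Precursor-like nuclei had the spectrin gene Sptb (0.52) and the transcriptional regulator Rai1 (0.42) highest and Kirrel3 (-0.47) and the syndecan Sdc3 (-0.46) lowest. With exercise the genotype ratios of Rai1 (0.16), Kirrel3 (0.015) and Sdc3 (-0.12) had intervals that included 0, and that of Sptb was -0.27. The precursor-like share at rest was 4.17% against 3.47%, a ratio of 1.20 (1.03–1.40), and the inhibitory-like share was 4.97% against 4.77%. Pyramidal-like nuclei had 17.4% against 16.3% and granule-like nuclei a ratio of 0.909 (0.872–0.948).

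**Figure D2:**
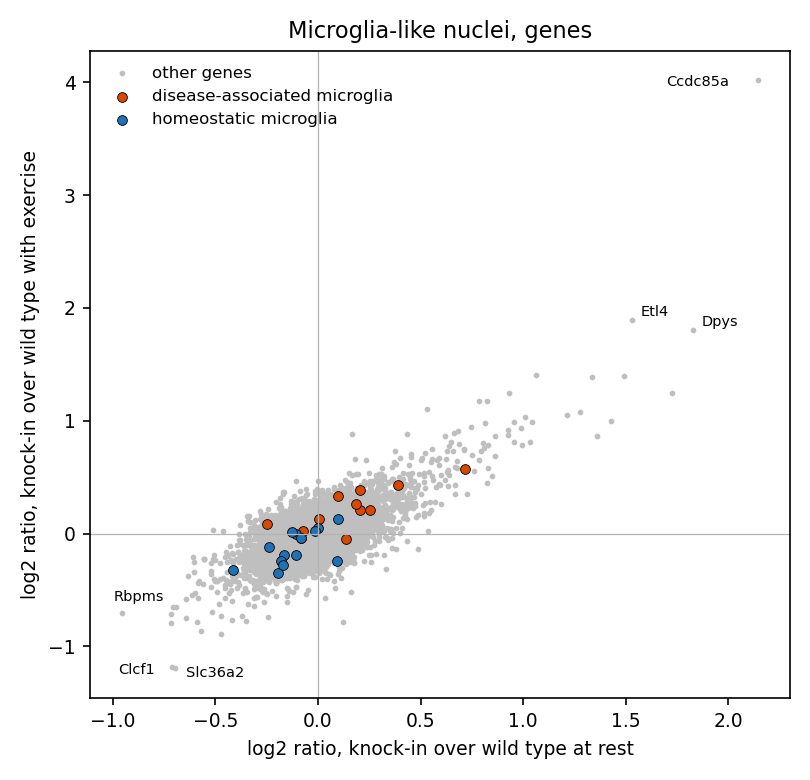
Log2 ratio of knock-in over wild type in microglia-like nuclei at rest (horizontal axis) and with exercise (vertical axis) for 7957 genes with at least 200 open calls per library on average; members of 2 gene lists that pass this minimum are coloured. Etl4 and Dpys lie high on both axes and Rbpms, Clcf1 and Slc36a2 low on both, while Ccdc85a stands apart at 2.15 and 4.02. Slc36a2 and Ccdc85a lie in divergent segments.

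The next comparison asked how wheel running related to chromatin in wild-type mice. It shares the library of wild type at rest with the first comparison, so values that went the same way in both are not independent. In granule-like nuclei, the neurons of the dentate gyrus that receive cortical input, 10 of 11 late activity-regulated genes were more accessible in the exercise library. Their median log2 ratio was 0.14 (0.08–0.19), at percentile 100 of the random lists. Bdnf, the brain-derived neurotrophic factor, was at 177 CPM (171–184) with exercise and 161 (155–167) at rest. Scg2, a neuropeptide precursor, had a log2 ratio of 0.28 (0.07–0.50), and Gadd45b, linked to DNA demethylation, of 0.23 (0.09–0.37). Immediate early genes were higher in 13 of 17 members, with a median of 0.06 (0.02–0.11), and the nuclear receptor Nr4a1 was at 36.6 (33.6–39.7) against 28.7 (26.4–31.2). These differences went with a shift between granule clusters, as cluster 2 held 50.9% of granule-like nuclei with exercise and 35.2% at rest. Within cluster 1 alone the late activity-regulated median was 0.03, and within cluster 2 alone it was 0.12.

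Other lists in granule-like nuclei had medians with intervals that included 0 with exercise in wild type. Exercise and growth factor genes had a median of -0.01 (-0.10 to 0.03), neurogenesis genes 0.05 (-0.09 to 0.09) and oxidative phosphorylation genes 0.04 (-0.01 to 0.10), with 5, 7 and 15 of 13, 13 and 20 members higher. Heat shock genes had a median of 0.08 (-0.00 to 0.15), glutamate synapse genes -0.00, GABA synapse genes -0.01, circadian genes -0.01 and glucocorticoid-responsive genes -0.03, although the means of the glutamate synapse, circadian and glucocorticoid lists were 0.01, 0.01 and 0.00. Marveld2, a tight junction protein, was among the highest single genes (log2 ratio 0.63, 0.37–0.89), and Nnmt, a nicotinamide methyltransferase, was among the lowest (-0.55, -0.81 to -0.29). Gm52481 had 1.18 here and 1.83 in pyramidal-like nuclei, and Gtf2a1l, in a divergent segment, had -0.81, with 0.27 from gene ends alone. Pyramidal-like nuclei had higher late activity-regulated genes in 10 of 11 members, with a median of 0.10 (0.04–0.17), and the scaffold gene Homer1 had 0.14 (0.02–0.27). Gal3st2c (0.65, and -0.14 from gene ends alone) was also high there, and Gm51425 (-0.43) and the asparaginase Asrgl1 (-0.41) were low. Of pyramidal-like nuclei, cluster 8 held 34.5% with exercise and 23.5% at rest, and cluster 11 held 15.9% and 22.9%. Values within single pyramidal-like clusters were not computed. Oligodendrocyte-like nuclei had higher immediate early genes in 13 of 17 members, with a median of 0.09 (0.00 to 0.14).

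Microglia-like nuclei differed little with exercise in wild type. Disease-associated genes had a median log2 ratio of -0.04 (-0.10 to 0.08) with 8 of 20 members higher, homeostatic genes -0.02 (-0.06 to 0.05) and interferon response genes 0.07 (-0.10 to 0.22). Anks1b (0.73, 0.43–1.04) and the phosphatase Ptprg (0.71, 0.35–1.08) were highest, and the glucocorticoid-responsive gene Zbtb16 (-0.61, -0.88 to -0.36) and Inppl1 (-0.50) were lowest. In oligodendrocyte-like nuclei Csf2ra, a cytokine receptor (0.44), and Alk (0.41) were highest and Zfp282 (-0.54) and Col4a1 (-0.53) lowest, and the last 3 of these lie in divergent segments. Astrocyte-like nuclei had Speg (0.36) and Hyal3 (0.32) highest and Atp11a (-0.41) and Man1a (-0.38) lowest, while the glutamate transporter Slc1a3 had 0.26 (0.14–0.39). The ratio of Atp11a was 0.04 with nuclei matched in depth. In precursor-like nuclei Sptb (0.56) and Brd2 (0.41) were highest and the kinase genes Mast4 (-0.47) and Camk1d (-0.43) lowest. Pyramidal-like nuclei made up 19.8% (18.9–20.7) against 16.3% (15.5–17.1), precursor-like nuclei 4.82% against 3.47% and granule-like nuclei 30.7% against 36.6%. The shares of microglia-like and astrocyte-like nuclei had ratios of 1.06 (0.942–1.19) and 0.993 (0.891–1.11).

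The third comparison asked how wheel running related to chromatin in the knock-in. Late activity-regulated genes in granule-like nuclei were higher in 7 of 11 members, with a median log2 ratio of 0.03 (0.00 to 0.13). Bdnf was at 167 CPM (160–173) with exercise and 153 (148–159) at rest, and Sorcs3, a sorting receptor of synapses, had a log2 ratio of 0.30 (0.22–0.39). Immediate early genes were higher in 11 of 17 members (median 0.03, -0.01 to 0.09), and Ier2 had 0.49 (0.28–0.70). Neurogenesis genes were higher in 10 of 13 members, with a median of 0.10 (0.02–0.19), although Dcx, a marker of young neurons, had 0.20 (-0.01 to 0.41) and its level was 25.2 against 21.9. Cluster 2 held 50.5% of granule-like nuclei with exercise and 37.7% at rest, and within it alone the late activity-regulated median was -0.03. With nuclei thinned to 2000 open peaks the same median was 0.18.

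Single genes that stood out in the knock-in with exercise included Zfp932 in granule-like nuclei, at 7.84 CPM (6.52–9.34) against 17.2 (15.3–19.3). That zinc finger gene was represented by 1 peak and was lower in all 7 classes, where every interval against the other 3 libraries held the pooled log2 ratio of -1.05. Gucy2c, a guanylate cyclase receptor, had a log2 ratio of -0.96 (-1.18 to -0.75) there and Gypc, in a divergent segment, of 0.68. Trhr2 had 0.67 with exercise in the knock-in and 0.63 in wild type, but it is among the 10 leading genes of granule cluster 2, and its values within single granule clusters were not computed. In oligodendrocyte-like nuclei Efemp1, an extracellular matrix protein, was at 8.63 CPM (6.11–11.8) with exercise and 58.3 (52.5–64.5) at rest, a log2 ratio of -2.74 (-3.28 to -2.27). Mpp7 had -0.65, Sccpdh 0.64 and Csf2ra 0.73 in that class, and the first 2 of these, like Efemp1, lie in divergent segments. Glucocorticoid-responsive genes in oligodendrocyte-like nuclei were higher with exercise in 9 of 11 members, with a median of 0.13 (0.06–0.20), and Zbtb16, a zinc finger factor, was at 383 (365–402) against 302 (288–315). In wild type Zbtb16 was at 352 with exercise and 382 at rest. Disease-associated oligodendrocyte genes were higher in 7 of 10 members (median 0.17, 0.03–0.29), cholesterol synthesis genes in 10 of 16 (0.07) and myelin genes in 9 of 16 (0.00). Between rest and exercise the shallow cluster 5 held 37.6% and 46.6% of this class.

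Microglia-like nuclei made up 14.4% (13.5–15.3) of the knock-in library with exercise and 11.8% (11.1–12.5) at rest, a ratio of 1.22 (1.12–1.33). Their disease-associated genes had a median log2 ratio of 0.02 (-0.04 to 0.09) with 11 of 20 members higher, and Spp1 was at 19.3 (15.8–23.4) against 19.8 (16.4–23.8). Interferon response genes were higher in 13 of 15 members, with a median of 0.16 (0.06–0.30), and Ifi44 had 49 calls against 28. Homeostatic genes had a median of -0.01 (-0.05 to 0.04) and plaque-induced genes of -0.07 (-0.13 to 0.01). Ccdc85a was at 156 CPM (146–167) against 47.0 (41.6–53.0), and the flippase Atp10a had a log2 ratio of 0.53. The adhesion gene Dscaml1 had -0.82 and the cytokine gene Clcf1 -0.61. Clcf1 is among the leading genes of a small cluster outside the classes, which held 29, 20, 1 and 4 nuclei of the libraries in order. In astrocyte-like nuclei App had a log2 ratio of 0.59 (0.28–0.92) and Otof, which encodes otoferlin, of 0.62, while Chst10 (-0.58) and Desi2 (-0.51) were lowest. The reactive and homeostatic astrocyte lists had medians of 0.00 (-0.21 to 0.13) and 0.03 (-0.06 to 0.13). In precursor-like nuclei Nf1, a regulator of Ras (0.41), and Dgki (0.37) were highest and 3110082I17Rik (-0.40) and Rab11fip4 (-0.40) lowest. Pyramidal-like nuclei had Cgn (0.55) and Obi1 (0.54) highest and H4f16 (-0.60) and the laminin Lamc3 (-0.59, and 0.14 from gene ends alone) lowest. The pyramidal-like share was 14.0% (13.2–14.9) against 17.4% (16.6–18.3), and the precursor-like share 5.34% against 4.17%. Cluster 8, the part of the pyramidal-like class whose share varied most, held 33.5% of it at rest and 22.1% with exercise.

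**Figure D3:**
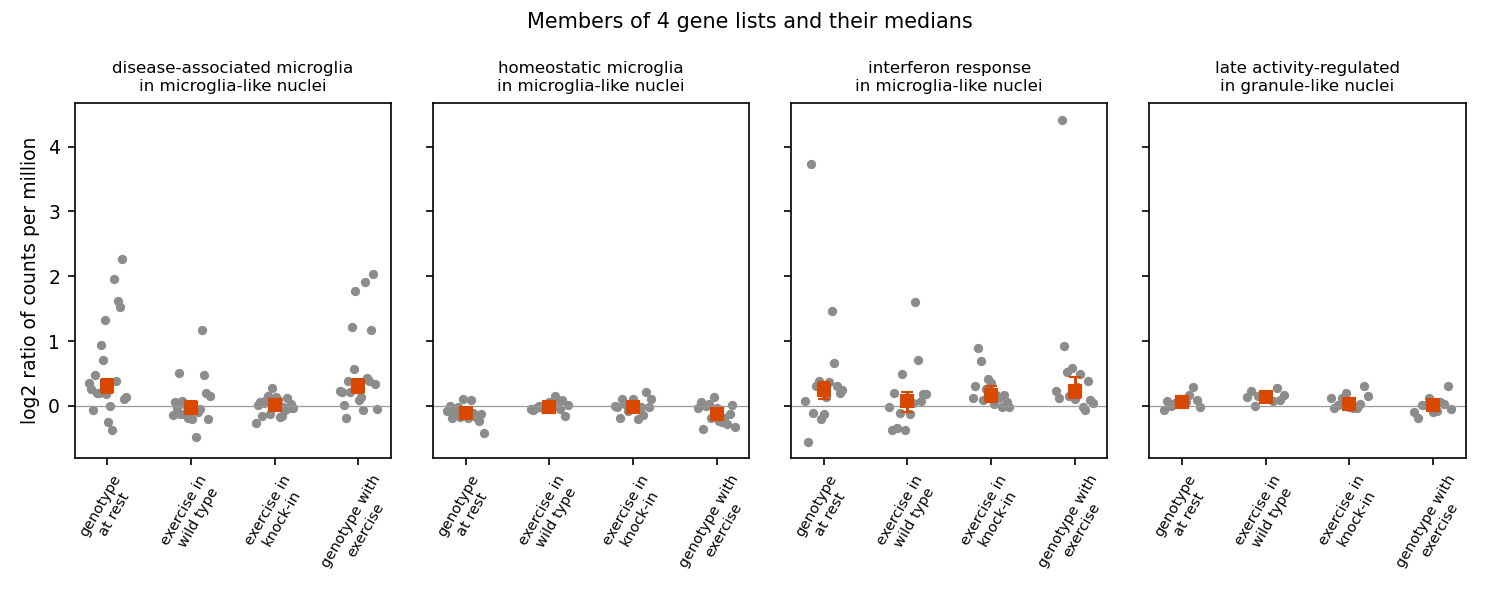
Log2 ratio (vertical axis) of each member (grey points) and the median (squares, with counting intervals) of 4 gene lists in the named class, for the 4 comparisons on the horizontal axis, 1 library per group. The disease-associated microglia medians were 0.30 for genotype at rest and with exercise against -0.04 and 0.02 for exercise in wild type and knock-in.

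The last comparison set the genotypes side by side with exercise. It shares the library of the knock-in with exercise with the third comparison. Values alike in both, such as those of Efemp1, Zfp932 and Ccdc85a, are therefore not independent. Microglia-like nuclei made up 14.4% of the knock-in library and 7.22% of the wild-type library, a ratio of 1.99 (1.80–2.21), and astrocyte-like nuclei 3.64% against 8.11%, a ratio of 0.449 (0.387–0.521). Disease-associated microglia genes were higher in the knock-in in 17 of 20 members, with a median log2 ratio of 0.30 (0.21–0.42). Spp1 was at 19.3 CPM against 4.60, Cst7 at 26.0 (21.9–30.7) against 7.47 (4.88–10.9) and Clec7a at 34.4 (29.6–39.8) against 14.7 (10.9–19.3). Homeostatic genes were lower in 11 of 15 members, with a median of -0.12 (-0.20 to -0.03), P2ry12 at 286 against 338 and Tmem119 at 67.5 against 84.2. Interferon response genes were higher in 13 of 15 members, with a median of 0.22 (0.13–0.45), which was 0.08 with members under 200 calls left out. Plaque-induced genes had a median of -0.10 (-0.14 to 0.03). Summed markers of oligodendrocyte precursors in these nuclei had 0.40 (0.22–0.57) and those of oligodendrocytes 0.23 (0.15–0.31), with a median of -0.18 over the markers. The sums of microglial, endothelial, dentate granule and astrocyte markers had -0.07, -0.12, -0.12 and 0.09 (-0.01 to 0.18), and the medians of endothelial and astrocyte markers were 0.02 and -0.22. Ccdc85a had a log2 ratio of 4.02 (3.54–4.59) and Etl4 of 1.89 (1.64–2.16), whereas Slc36a2, an amino acid transporter (-1.20), and Clcf1 (-1.18) were lowest. Slc36a2, like Ccdc85a, lies in a divergent segment.

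In other classes many of the largest genotype differences with exercise lay in divergent segments. Oligodendrocyte-like nuclei had Gm40369 (1.38) and Col4a1 (1.30) highest and Efemp1 (-3.17, -3.71 to -2.70) and Mpp7 (-1.43) lowest, all of them in such segments. Disease-associated oligodendrocyte genes were higher in the knock-in in 8 of 10 members (median 0.27, 0.07–0.49), with H2-D1 at 39.5 against 14.8 CPM and Serpina3n at 32.5 (27.4–38.3) against 19.6 (15.9–23.9). With the members below 200 calls on average left out, the median was -0.05. The shallow cluster 5 held 46.6% of oligodendrocyte-like nuclei in the knock-in and 32.7% in wild type. Granule-like nuclei had Efemp1 at -1.16 and Zfp932 at -1.06, and their late activity-regulated and immediate early medians were 0.01 and -0.02. Pyramidal-like nuclei had St3gal6 (-0.58) and Ptchd4 (-0.57) lowest. Astrocyte-like nuclei had Epb41l4a (0.71) and Osbpl3 (0.57) highest and Vit (-0.74, and 0.16 from gene ends alone) and the receptor Notch4 (-0.61) lowest, all 4 in divergent segments. Precursor-like nuclei had the adhesion gene Nrcam (0.39) and Sorcs1 (0.37) highest and Rab11fip4 (-0.59) and Prdm16 (-0.44) lowest. Pyramidal-like nuclei made up 14.0% against 19.8%, a ratio of 0.707 (0.655–0.764). Cluster 8 held 22.1% of them in the knock-in and 34.5% in wild type.

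For genotype by exercise, the exercise ratio in wild type was subtracted from that in the knock-in, a value with no test. Late activity-regulated genes in granule-like nuclei gave -0.12 (-0.16 to 0.01) and disease-associated genes in microglia-like nuclei 0.06 (-0.08 to 0.15). The late activity-regulated value was 0.04 with nuclei thinned to 2000 open peaks. Across 7957 genes in microglia-like nuclei, the genotype ratios at rest and with exercise, which share no library, had r = 0.678 and rho = 0.528 (r = 0.446 from gene ends alone), and the exercise ratios in both genotypes r = 0.109 and rho = 0.096. Across 13732 genes in granule-like nuclei, r was 0.300 (rho 0.208) for genotype and 0.323 (rho 0.298) for exercise, and with nuclei thinned to 2000 open peaks 0.160 and 0.177. Median open peaks in granule-like nuclei were higher with exercise in both genotypes, at 7078 against 5862.5 in wild type and 7423 against 5633 in the knock-in. The part held by granule cluster 2 was also higher, at 50.9% against 35.2% and 50.5% against 37.7%. In oligodendrocyte-like nuclei r was 0.293 (rho 0.155) for genotype and 0.174 (rho 0.174) for exercise, and in pyramidal-like nuclei 0.096 (rho 0.055) and 0.097 (rho 0.098). Astrocyte-like nuclei had 0.087 (rho 0.060) and 0.046 (rho 0.054), precursor-like nuclei 0.121 (rho 0.132) and 0.021 (rho 0.017), and inhibitory-like nuclei 0.105 (rho 0.087) and -0.018 (rho -0.013). From gene ends alone the exercise r was -0.336 in precursor-like and 0.288 in inhibitory-like nuclei. These correlations are across genes, which are not independent replicates. Across the 38299 peaks with at least 100 calls in microglia-like nuclei, r was 0.652 for genotype and 0.024 for exercise, and across 129647 peaks in granule-like nuclei 0.202 and 0.250. With at least 500 calls per peak these were 0.501 and 0.058 in microglia-like and 0.323 and 0.337 in granule-like nuclei.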

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

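The tests of explanations for the astrocyte-like share in this part were all chosen after the result was seen. Among 274 pairs of values for the same contrast in 2 settings, 3 had counting intervals on opposite sides of no difference. The granule-like share was lower in the knock-in at rest, with a ratio of 0.909 (0.872–0.948), and higher in the knock-in with exercise, with a ratio of 1.079 (1.027–1.134). Sptb in precursor-like nuclei had a genotype log2 ratio of 0.516 (0.213–0.828) at rest and -0.271 (-0.517 to -0.026) with exercise. The pyramidal-like share was higher with exercise in wild type, with a ratio of 1.213 (1.133–1.299), and lower with exercise in the knock-in, with a ratio of 0.803 (0.743–0.867). Cluster 8, named by markers of subicular or cortical excitatory neurons, went the same way. It held 308 nuclei at rest and 484 with exercise in wild type (23.5% and 34.5% of the class), and 489 and 195 in the knock-in (33.5% and 22.1%). These 3 differences between settings were not tested, since each value rests on 1 library per group, and shares of classes depend on each other.

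Astrocyte-like nuclei made up 8.17% and 8.11% of the wild-type libraries and 3.31% and 3.64% of the knock-in libraries. The larger of the 2 genotype ratios was 0.464 among nuclei with at least 3000 open peaks. This value cannot decide on a loss of shallow nuclei, because a stricter minimum does not bring back nuclei already lost. That explanation stays open. Dilution by microglia-like nuclei is argued against by a ratio of 0.486 outside that class, and nuclei left in unnamed clusters by a ratio of 0.453 with every cluster led by astrocyte markers counted. A difference in dissection or in recovery of nuclei between libraries and a difference between genotypes both stay open, as neither was tested.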

How the results depend on the processing

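Alternatives that matched nuclei in depth, took shares within part of the classes, used single granule clusters or left out divergent segments were chosen after seeing the data. Of the values that answer a comparison, 292 stayed within their counting interval under an alternative, 35 left it, 10 of them to the other side of no difference, and 5 reversed, a word kept for values whose interval excluded no difference; for single genes and other lists or correlations the numbers were 2182, 149 (52) and 13. All 28 share ratios stayed within their intervals with 20 or 50 components, with no doublets removed and at resolution 0.5, as did all 442 log2 ratios with median-of-ratios size factors. Where a value moved or reversed, the cause was not tested. With a minimum of 3000 open peaks, the granule-like share ratio was 0.949 (genotype at rest), 0.918 (exercise in wild type) and 1.081 (exercise in knock-in), the precursor-like ratio 1.752 and 1.815 (exercise in wild type and knock-in), and the oligodendrocyte-like ratio below 1 for exercise (0.811 and 0.809, against reported 1.063 and 1.025 with intervals that included 1) and, reversed, 0.955 and 0.952 for genotype at rest and with exercise. Outside the microglia-like class, the genotype ratios were 0.96 and 1.169 (granule-like, at rest and with exercise), 0.767 (pyramidal-like, with exercise) and 1.16 (oligodendrocyte-like, with exercise). Among glial classes alone, the oligodendrocyte-like ratio was 1.031 (genotype at rest), 0.987 and 0.92 (exercise in wild type and knock-in) and, reversed, 0.96 (genotype with exercise), and the microglia-like ratio 1.096 (exercise in knock-in) and 1.787 (genotype with exercise). At resolution 2 the inhibitory-like ratio for genotype at rest was 0.904. With nuclei thinned to 2000 open peaks, the late activity-regulated median in granule-like nuclei was 0.176 (exercise in knock-in) and its genotype-by-exercise value 0.041, the disease-associated microglia median -0.054 (exercise in knock-in), the interferon response median 0.047 (genotype at rest) and the immediate early median in astrocyte-like nuclei, reversed, -0.087 (genotype at rest). Thinned correlations for genotype and exercise were 0.16 and 0.177 in granule-like and 0.61 and 0.065 in microglia-like nuclei. Thinning left out 277, 397, 492 and 441 oligodendrocyte-like nuclei and 11, 19, 48 and 44 microglia-like nuclei of the libraries in order. With list members under 200 calls left out, the disease-associated oligodendrocyte median was -0.06 (genotype at rest) and, reversed, -0.047 (genotype with exercise), the disease-associated microglia median 0.187 (genotype at rest) and the interferon response median 0.085 (genotype with exercise). With gene ends only, r was 0.269 (exercise, granule-like), 0.446 (genotype, microglia-like) and 0.074 (exercise, microglia-like), and these reversed: glutamate synapse genes at rest in pyramidal-like (0.005) and precursor-like nuclei (-0.094), Qpct in granule-like (0.245), Vit in astrocyte-like nuclei at rest (2.169) and with exercise (0.162), Gtf2a1l in granule-like (0.273) and Gal3st2c in pyramidal-like nuclei (-0.135) for exercise in wild type, and Lamc3 in pyramidal-like nuclei (0.145) for exercise in the knock-in. With nuclei matched in depth, r in microglia-like nuclei was 0.624 (genotype) and 0.056 (exercise), and the exercise r in astrocyte-like nuclei (-0.023) and Atp11a there (0.038, exercise in wild type) reversed. In granule cluster 1 alone the late activity-regulated median for exercise in wild type was 0.033; in cluster 2 alone the medians for exercise in the knock-in were -0.028 (late activity-regulated, reversed) and -0.033 (immediate early). For peaks with at least 500 counts, r in precursor-like nuclei reversed to -0.145 (genotype) and -0.06 (exercise). Binarised values were not run because the values were already binary, the alternative of keeping all barcodes left every nucleus in place, motifs were not run without a genome sequence, and leaving out a replicate gave no value with 1 library per group. No paired analysis was possible because the sources used here gave no pairing of mice between groups. Depth limits the precursor-like, inhibitory-like and astrocyte-like classes most among the 7, with 936, 1149 and 3545 genes at 200 calls on average against 13732 in granule-like nuclei.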

Other observations

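All tests of explanations in this part were chosen after the result was seen. Peaks that differed between the knock-in libraries and wild type crowded in a few segments of the genome. Summed over the classes and set against both wild-type libraries, 240 of 232531 peaks differed by more than 1.5 on the log2 scale in the knock-in at rest and 250 of 209522 in the knock-in with exercise, against 37 of 228850 between the wild-type libraries. Of these peaks 185, 198 and 36 were lower, and the higher ones were not tested. All of chromosome 17 held 100, 71 and 2 such peaks, where its share of the tested peaks would give 9.01, 9.48 and 1.39, and chromosome 1 held 45, 26 and 3 (17.7, 18.2 and 2.71). A peak on chromosome 17 from 33980901 to 33981809 had 1580 and 1335 calls in the wild-type libraries and 4 and 3 in the knock-in libraries.

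On chromosome 17 lay 58 of the 200 granule-like peaks with the largest genotype differences of 1 sign in both pairs of libraries, against 7.37 from its share of peaks. The counts were 35 (9.48) in oligodendrocyte-like, 23 (7.25) in pyramidal-like and 18 (9.66) in microglia-like nuclei. For exercise they were 3 in granule-like, 10 in oligodendrocyte-like, 7 in pyramidal-like and 13 in microglia-like nuclei. A difference in depth is argued against as the whole cause in granule-like nuclei, because 47 of the 200 peaks lay there with nuclei matched in depth, against 7.47. The matched counts were nearer to the share of peaks in oligodendrocyte-like (25, against 9.62), pyramidal-like (15, against 7.84) and microglia-like nuclei (17, against 9.78). Sequence differences from the reference shared by both knock-in libraries are a candidate explanation for the lower peaks alone, since they would lower a peak in every class. Peaks were chosen as lower in the sum of 6 classes and read in the class left out, and 94.0% of 50 such pairs were lower in both knock-in libraries. The pairs came from 24 peaks and are not independent, and all classes come from the same libraries. Sequence was not read, and a regulatory difference common to all classes stays open.

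Other segments differed in 1 knock-in library: all of chromosome 11 held 4 peaks past the same limit at rest and 71 with exercise (15.9 from its share of peaks), chromosome 10 held 29 (12.2) and 4, and chromosomes 6 and 18, with 18 (14.5) and 12 (8.85) with exercise, were less crowded. At 45 peaks of chromosomes 6, 11 and 18 chosen as lower in the knock-in with exercise than at rest, the median log2 ratio was -2.13 by that choice. In wild type it was -0.003, which argues against wheel running acting alike in both genotypes at these peaks alone. The chromosomes were picked for differences from both wild-type libraries, which selects against peaks that running lowers in wild type too. With all nuclei the divergent segments held 18, 67 and 9 such peaks on chromosomes 6, 11 and 18 with exercise and 28 on chromosome 10 at rest. With nuclei matched in depth 100 peaks were past the limit in them, which argues against depth as the whole cause. The 8.21 from their share of peaks is no neutral standard, since the segments were chosen for such peaks in the same libraries. Sequence differences carried by the mice of 1 library may explain the lower peaks, as 92.0% of 87 pairs chosen in the same way were lower in the class left out. These pairs came from 49 peaks and are not independent. Exercise acting in the knock-in alone was not tested apart from such sequence differences. Some genes of these segments that were named for an extreme ratio differed between classes. Against the other 3 libraries Ccdc85a had a log2 ratio of 2.58 in microglia-like and 0.03 in granule-like nuclei. Mpp7 had -1.94 in microglia-like and 0.02 in pyramidal-like nuclei, and Efemp1 -2.97 in oligodendrocyte-like and 0.30 in astrocyte-like nuclei. Others were more alike, as the interval left out the ratio pooled over classes in 1 of 7 classes for Gm40369 and in 0 of 7 for Zfp282. These ratios sum all peaks of a gene, so a change alike in every class at a single peak could also make them differ. The cause stays open at these genes.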
